A study of Mus musculus with 6 samples.

How the data were processed

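RNA was measured in the neocortex of 6 mouse embryos at embryonic day 14.5, with 1 Affymetrix Mouse Gene ST array per embryo. The series text states that RNA was prepared from each embryo separately, so the 3 control and 3 mutant arrays were treated as biological replicates. Per the labels, the controls were wild type for Bcl11a and the mutants carried the deleted form of a floxed Bcl11a allele on both chromosomes. Per the labels' protocols, total RNA was extracted with a column kit and labelled with biotin in a whole-transcript sense-strand assay. The Cre line, the cells in which the allele was deleted, the deleted exon and the sex of the embryos are not given in the sources used here.

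Per the submitters' processing notes, the authors processed the arrays with Affymetrix Expression Console and RMA, which corrects the background, applies quantile normalization and summarises the probes of a probe set. The deposited values were taken to be on the log2 scale, since RMA gives log2 values and the values of each array lay between 3.41 and 13.8. Software versions and the genome build behind the array are not given in the sources used here, so no coordinates are printed. The series text names BRB-ArrayTools for the authors' own comparison, but no test or threshold, so their comparison was not repeated. The medians of the 6 arrays lay between 7.23 and 7.33, so no further scaling was applied for the reported values. RMA compresses differences near the background, so changes of dim genes are understated. Its quantile step makes the arrays' distributions alike, so a shift of most genes in 1 direction would not be seen. For arrays there is no read depth, and the number of arrays limits the precision.

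Probe sets were named from GEO's platform annotation, which can be old. Of 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 had no gene listed here. The symbols of 21698 probe sets were matched through their Entrez numbers to a RefSeq gene table of assembly GRCm38.p6, which was used only for names and gene order. None of these symbols had to be updated, and 91 probe sets kept the symbol of the annotation. Probe sets with several genes or no gene were left out of the comparison. For the 999 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used, which left 19938 genes.

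Mutants were compared with controls in limma 3.58.1 under R 4.3.3, with lmFit and eBayes on the 6 arrays and no covariate. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and an adjusted p under 0.05 counted as a change. Every adjusted p for a gene comes from this limma fit, is two-sided and is given with the log2 difference of mutant minus control. Errors beside group means are SDs over 3 arrays, and errors of differences are limma's moderated standard errors. Exact two-sided permutation tests of 3 against 3 arrays were run for Bcl11a, Bcl11b and Sema3c. Gene lists were tested with camera in limma, with the preset correlation of 0.01, which compares the list with all other genes. Camera was repeated with a correlation estimated from the data, and fry was run as a test of whether the genes of a list moved to 1 side on balance. P-values were adjusted over the 31 lists. The limma p-values of list members were also adjusted over each list alone by the Benjamini-Hochberg method, without correction across lists. A gene held by several lists was counted in each.

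The groups, the design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. Bcl11a, Bcl11b and Sema3c were always named. Of the genes past the threshold, the 12 with the largest rise and up to 12 with the largest fall were named, without predicted or unnamed models, small RNAs, olfactory and vomeronasal receptors or antigen receptor segments. From each list, up to 6 members past the threshold and up to 2 further members were named. Genes named outside this rule were chosen after their values were seen. These were the list members Alas2, Cdh8, Efna5, Eomes, Etv5, Igf2, Lhx9, Lpl, Nhlh2, Pax6, Reln, S100a10, Sox2 and Tbr1, and Dlk1, Fam160a1, Gm32061, Lratd1 and Rit2. Xist was used only to read the sex of the embryos. The lists held 623 entries, of which 590 were measured. They covered semaphorins and their receptors, ephrins and Eph receptors, slit, netrin and FLRT guidance, cadherins and protocadherins, radial migration, p53 targets and cell death, immediate early and heat shock genes, the cell cycle, Notch and Wnt signalling, cortical area patterning, BAF chromatin remodelling subunits and genes tied to Bcl11a in earlier work. Cell type lists covered radial glia, intermediate progenitors, pan-neuronal genes, subcerebral, corticothalamic, subplate and callosal neurons, Cajal-Retzius cells, GABAergic interneurons, ganglionic eminence and striatum, thalamus, hippocampal primordium and cortical hem, choroid plexus, erythroid cells, endothelial cells, pericytes and meninges, microglia and macrophages, and oligodendrocyte precursors. Genes of the lists without a single-gene probe set were not tested as single genes or counted in the lists. The probe sets shared by adult globin genes were examined separately.

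The alternatives were leaving out each array in turn, the replicate number as a block, quantile normalization or median centring of the deposited table, filters on dim genes, an intensity trend or a robust prior in eBayes, array weights, the embryos' sex as read from Xist and Y-linked genes, the mean of a gene's probe sets, all probe sets singly, other thresholds, and other list tests. Leaving out the erythroid list, alone or with mutant replicate 1, was added after the data were seen.

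The scripts were tested on simulated data with the means of the 19938 genes and noise drawn from limma's moderated variances, in 10 runs with 200 changed genes each. They recovered 94% of genes changed by 0.5 on the log2 scale, 99.6% at 1, 99.8% at 1.5 and 100% at 2, with 6.10% false calls. A list shifted by 0.5 was called in 10 of 10 runs, and 0 other lists were called. The simulated genes varied independently of each other, without differences between whole arrays. The 200 changed genes per run exceed the 57 called in the data. The recovery rates hold for that setting and do not give the share of changed genes found in the data. In the data the estimated correlation within a list reached 0.70, for Cajal-Retzius cells. These runs therefore do not show how often lists of correlated genes are called falsely. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.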

Results

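Gene expression was measured in the neocortex, the part of the forebrain that forms most of the cerebral cortex, of 6 mouse embryos at embryonic day 14.5. Of these embryos, 3 were wild-type controls and 3 were mutants that carried a deleted Bcl11a allele on both chromosomes. Each embryo gave 1 array of log2 expression values, and correlations between arrays ranged from 0.993 to 0.997. The first principal component held 29.4% of the variance and did not separate the genotypes. It set mutant replicate 1, at 29.8, apart from control replicate 3, at -22.0. By Xist and Y-linked genes, 2 controls and 1 mutant were female, and 1 control and 2 mutants were male.

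Mutants were compared with controls to find genes that depend on Bcl11a, a zinc finger transcription factor of cortical projection neurons. The study's title names Sema3c, a secreted semaphorin that guides migrating neurons and axons, as a gene under its control. Bcl11a (Entrez 14025) fell by 0.84 on the log2 scale in the mutants, from 12.25 ± 0.05 to 11.41 ± 0.08 (SD, n = 3 arrays each), with a limma adjusted p of 0.00201. This was 1.79-fold lower, and its values were 12.20, 12.30 and 12.26 in the controls and 11.41, 11.49 and 11.34 in the mutants. Where its probes lie relative to the deleted part is not given in the sources used here, and probes outside that part would keep their signal and check nothing. Sema3c (Entrez 20348) rose 2.41-fold, from 9.06 ± 0.19 to 10.33 ± 0.11 (SD, n = 3 arrays each), a log2 difference of 1.27 ± 0.10 (SE, limma adjusted p = 0.00201). Bcl11b, the paralog that marks subcerebral projection neurons, differed by 0.29 and did not pass (limma adjusted p = 0.219). The calls of Bcl11a and Sema3c held in each of 18 alternative fits. For each of the genes Bcl11a, Sema3c and Bcl11b the groups did not overlap, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 arrays can give.

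Across the 19938 genes, 57 passed the threshold, of which 49 were higher and 8 were lower in the mutants. The largest rise belonged to an embryonic globin gene, Hbb-bh1. Of the calls, 38 were at least 1.5-fold and 11 were at least 2-fold, and these 11 were all higher in the mutants. The mutant and control arrays did not overlap for any of the 57 genes. Over all genes, 10.5% had groups that did not overlap, where chance gives 10%. The median log2 difference of all genes was 0.02, and 60.3% of genes had a positive difference.

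**Figure D1:**
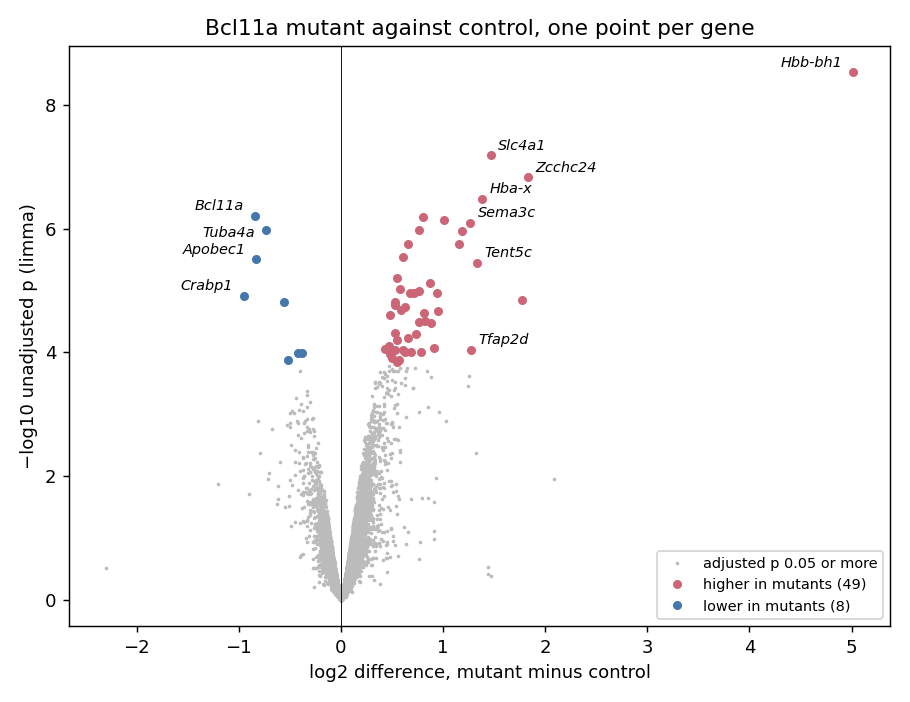
Each point is 1 of 19938 genes, with the log2 difference of mutant minus control on the x axis and the negative log10 of the unadjusted limma p on the y axis. Red points are the 49 genes that were higher and blue points the 8 that were lower at an adjusted p under 0.05. Hbb-bh1 lies far to the right at 5.02, and Bcl11a lies on the left at -0.84.

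Genes of red blood cells rose. Hbb-bh1, an embryonic beta-like globin, rose 32.3-fold, from 6.26 ± 0.43 to 11.27 ± 0.26 (SD, n = 3 arrays each), with a log2 difference of 5.02 ± 0.20 (SE, limma adjusted p = 5.92e-05). Hba-x, the embryonic alpha-like globin zeta, rose by 1.38 on the log2 scale and is 1 of the 200 tested genes nearest to Bcl11a on its chromosome. Slc4a1, the band 3 anion exchanger of the red cell membrane, rose by 1.47. Kel, Rhag and Epb42, which encode red cell surface or membrane skeleton proteins, rose by 0.66, 0.62 and 0.55. Of the 20 genes fixed for erythroid cells, 9 were measured, 6 rose and none fell. Adult globins, which have only probe sets shared by several genes, were not among these 9, and their probe sets differed by 0.05 to 0.26. All 9 were higher adjusted over the list alone, and the list median was 0.71. Hbb-y, Car2 and Alas2, with differences of 0.59, 1.24 and 0.71, did not pass over all genes. The list was higher by camera (adjusted p = 3.57e-32) and kept its call with an estimated correlation (adjusted p = 0.00711). Rhag did not pass without mutant replicate 2 or 3 (highest adjusted p 0.0864), and Epb42 passed in none of the 6 fits that left out 1 array (highest adjusted p 0.212).

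The other large rises came from genes with varied roles. Zcchc24, a zinc finger protein gene, rose 3.56-fold, from 7.61 ± 0.23 to 9.44 ± 0.14 (SD, n = 3 arrays each). Tent5c, which encodes a poly(A) polymerase, rose by 1.33 on the log2 scale, and Tfap2d, a transcription factor of the AP-2 family, by 1.27. Hmox1, the inducible heme oxygenase that breaks down heme, rose by 1.19. Gamt, an enzyme of creatine synthesis, rose by 1.16. Fgfbp3, a binding protein of fibroblast growth factors, rose by 1.01. Egln3, a prolyl hydroxylase that acts on hypoxia-inducible factors, rose by 0.95, and Gdpd2, a glycerophosphodiester phosphodiesterase, by 0.94. The limma adjusted p of these genes lay between 0.000968 for Zcchc24 and 0.0393 for Tfap2d. Tfap2d did not pass without control replicate 1, 2 or 3 or mutant replicate 2, with an adjusted p of up to 0.145. Egln3 did not pass without control replicate 2 or any 1 mutant (up to 0.0952), nor Gdpd2 without mutant replicate 1 or 2 (up to 0.068).

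The genes that fell were Bcl11a and 7 others, all by less than 2-fold. Crabp1, a cellular binding protein of retinoic acid, fell by 0.95 on the log2 scale, from 10.45 ± 0.08 to 9.50 ± 0.22 (SD, n = 3 arrays each). Apobec1, a cytidine deaminase that edits RNA, fell by 0.83, and Tuba4a, an alpha-tubulin, by 0.74. Gipr, the receptor of an incretin hormone, fell by 0.55. Myc, a transcription factor of growth and proliferation, fell by 0.52. Car12, a membrane carbonic anhydrase, fell by 0.42, and Shc3, a neuronal adaptor of receptor tyrosine kinases, by 0.38. Apobec1 and Tuba4a passed in each of the 6 fits that left out 1 array. Crabp1 did not pass without control replicate 2 or mutant replicate 2 (up to 0.069), and Gipr without control replicate 2 or any 1 mutant (up to 0.0824). Car12 passed only in the fit without control replicate 1 (up to 0.2001 in the others), and Myc and Shc3 in none (up to 0.207).

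**Figure D2:**
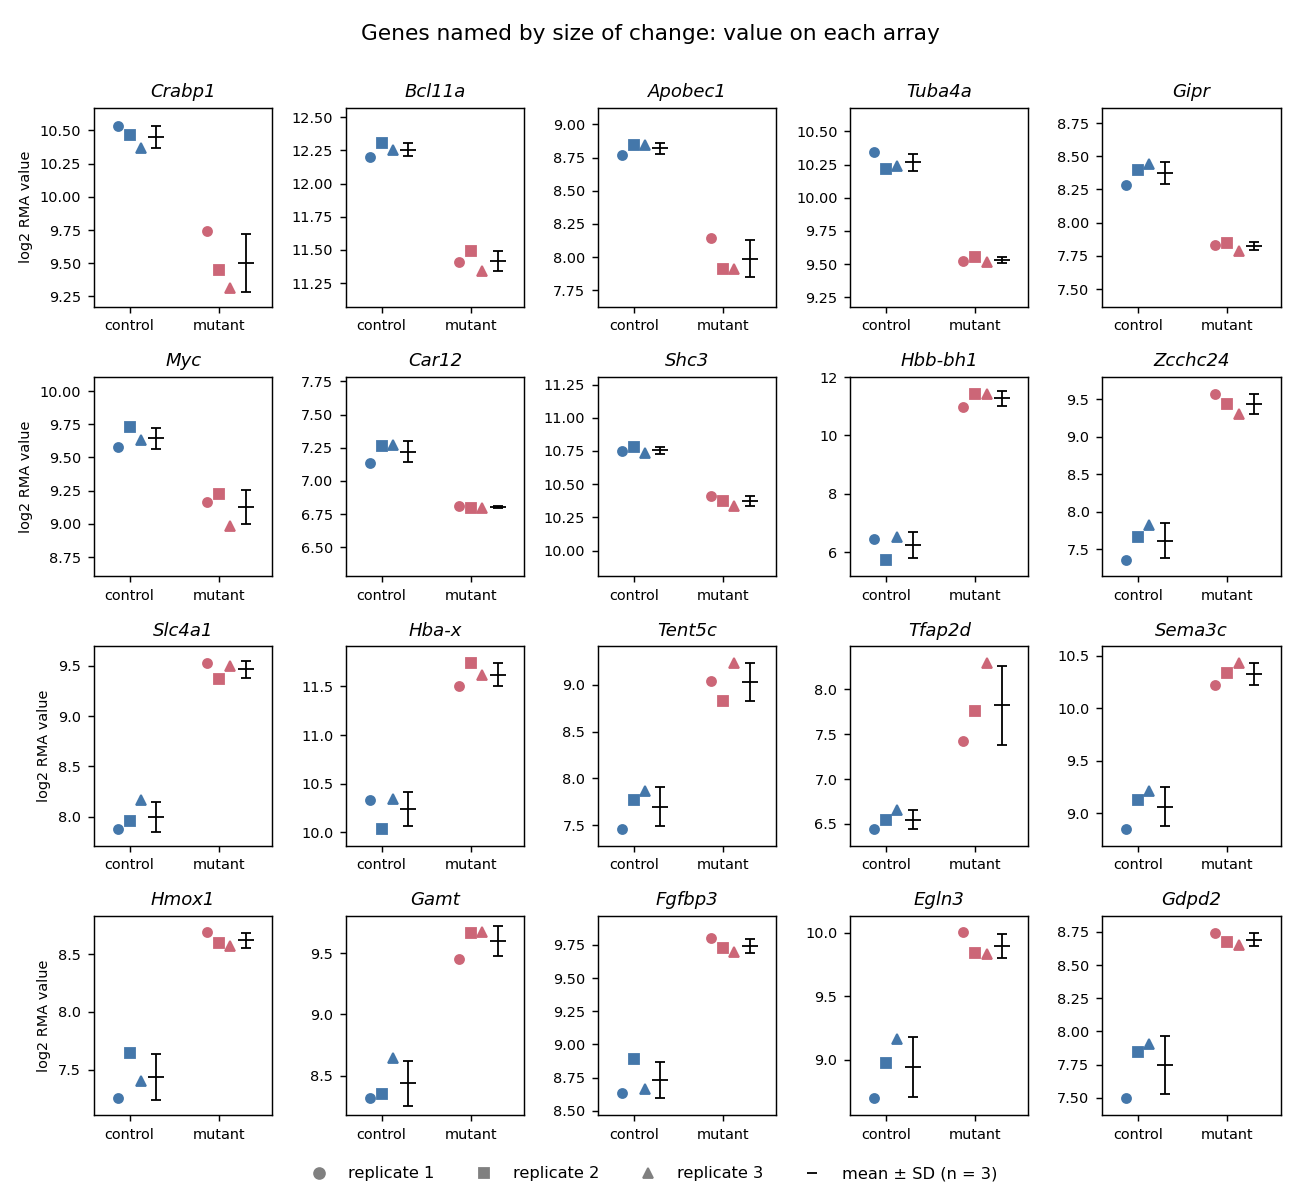
The panels show the log2 value on each of the 3 control and 3 mutant arrays for the 8 genes that fell and the 12 genes named for the largest rise, with the mean and SD beside the points. In every panel the control and mutant arrays are apart, and the axis ranges differ between panels. Tfap2d has the widest spread among these mutants, with an SD of 0.44.

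Most guidance and adhesion genes of the lists had positive differences, as did 60.3% of all genes tested. Among 31 semaphorins and their receptors, 2 rose, Sema3c and its receptor gene Nrp2, which rose by 0.59 (limma adjusted p = 0.0135), and none fell. Adjusted over the list alone, 3 were higher, with Sema3a at 0.28 as the further gene. Sema3c was chosen by the study on these samples, so this count and the list tests that follow are not independent evidence of the list's direction. The list was not tested without Sema3c. The list was higher by camera (adjusted p = 8.37e-05), with an adjusted p of 0.184 with an estimated correlation and of 0.0355 by fry. Nrp2 did not pass without control replicate 2 or any 1 mutant (up to 0.0864). No member of the cadherin, slit and ephrin lists passed over all genes. Of 24 cadherins and protocadherins, 18 had positive differences and 4 were higher adjusted over the list alone, led by Cdh4 at 0.37 and Cdh10 at 0.42. Camera gave an adjusted p of 0.000711, and an adjusted p of 0.326 with an estimated correlation. Of 24 slit, netrin and FLRT guidance genes, 19 had positive differences, and Slit3, at 0.45, was the 1 gene higher adjusted over the list alone. Unc5d, a netrin receptor gene, differed by 0.22. Camera gave an adjusted p of 0.00275, and an adjusted p of 0.198 with an estimated correlation. Of 19 ephrins and Eph receptors, 12 had positive differences and 4 were higher adjusted over the list alone, among them Ephb6 at 0.31 and Efnb3 at 0.27. Camera gave an adjusted p of 0.0256, and an adjusted p of 0.429 with an estimated correlation. The ephrin call was lost without control replicate 2 (adjusted p = 0.210, median 0.04 in place of 0.10) and without mutant replicate 1 (0.0978, median 0.07).

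By camera the intermediate progenitor list was higher and the cell cycle and radial glia lists were lower, with adjusted p of 0.458, 0.429 and 0.512 with an estimated correlation. Neurod4, a proneural transcription factor, rose by 0.66 (limma adjusted p = 0.0294) and was the 1 member of 18 intermediate progenitor genes to pass. Adjusted over the list alone, 5 were higher and 1 was lower, with Dll3 at 0.53, Slc17a6 at 0.37 and Eomes, a defining gene of these cells, at 0.21. Camera gave an adjusted p of 0.000941. The list call was lost without control replicate 2 (adjusted p = 0.0723), and Neurod4 passed only in the fit without control replicate 3 (up to 0.134 in the others). None of 27 cell cycle genes passed, and 5 had positive differences. Ccnd1, the cyclin D1 gene, at -0.41, was the 1 gene lower adjusted over the list alone, and the S-phase gene Mcm3 differed by -0.22. Camera gave an adjusted p of 7.82e-07. The list median was -0.07, and -0.03 without control replicate 1. None of 22 radial glia genes passed, and Hopx, at -0.43, was the 1 gene lower adjusted over the list alone. Sox2 and Pax6, core transcription factors of these cells, differed by 0.00 and 0.02. Camera gave an adjusted p of 0.00634, with a median of -0.01. This call was lost without control replicate 1 (adjusted p = 0.0679) and without mutant replicate 3 (0.289), where the median was 0.01 and 0.02. The other fits that left out 1 array kept the call, with medians between -0.06 and -0.01.

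Among neuron lists, those of corticothalamic and Cajal-Retzius neurons were lower by camera, with adjusted p of 0.156 and 0.516 with an estimated correlation. None of 15 corticothalamic genes of layer VI passed, over all genes or adjusted over the list alone, and 3 had positive differences. Hs3st4 and Ppp1r1b differed by -0.30 and -0.20, and Tbr1, a defining transcription factor of these neurons, by 0.00. The preset-correlation adjusted p was 2.77e-05, and the list median of -0.10 was -0.16 without control replicate 1. None of 11 genes of Cajal-Retzius cells, the reelin-secreting neurons of the cortical surface, passed over all genes. Adjusted over the list alone, 6 were lower, with Calb2 at -0.68, Lhx5 at -0.37 and Reln at -0.32, and 2 were higher, with Lhx1 at 0.20 and Nhlh2 at 0.31. The control and mutant values of Lhx5 overlapped. Camera's adjusted p was 0.000381, with a median of -0.21. The call was lost without control replicate 3 (adjusted p = 0.0920, median -0.14). Callosal and upper-layer genes did not pass by camera (adjusted p = 0.0742), although fry gave an adjusted p of 0.0355. Of these 26 genes, adjusted over the list alone, Lmo4 at 0.30 and Dkk3 at 0.26 were higher and Lpl at -0.79 was lower. Subcerebral genes of layer V did not pass either (adjusted p = 0.717), and adjusted over the list alone Bcl11b and Qrfpr were higher and Pcp4 and S100a10 were lower.

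The microglia and macrophage list and the pericyte and meninges list were higher by camera, with adjusted p of 0.326 and 0.512 with an estimated correlation. None of 17 genes of microglia and macrophages passed, over all genes or adjusted over the list alone, and all 17 had positive differences, with Csf1r at 0.29 and Fcrls at 0.45. The preset-correlation adjusted p was 2.36e-07. The median was 0.21, and 0.13 without mutant replicate 1. None of 19 genes of pericytes and meninges passed, over all genes or adjusted over the list alone, and 18 had positive differences. Dcn, a proteoglycan of connective tissue, was at 6.61 ± 0.02 in controls and 8.69 ± 1.64 in mutants (SD, n = 3 arrays each), and read 10.49, 8.32 and 7.27 in mutant replicates 1, 2 and 3. The preset-correlation adjusted p was 1.45e-05. The list median was 0.26, and 0.07 without mutant replicate 1, where the list still passed (adjusted p = 0.0114). The endothelial list did not pass (adjusted p = 0.157), with 16 of 17 genes positive and a median of 0.08, which was -0.0084 without mutant replicate 1. Tek, an angiopoietin receptor gene, was at 0.32, and Mfsd2a, a lipid transporter of brain vessels, at -0.33, was the 1 gene that passed adjusted over the list alone.

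**Figure D3:**
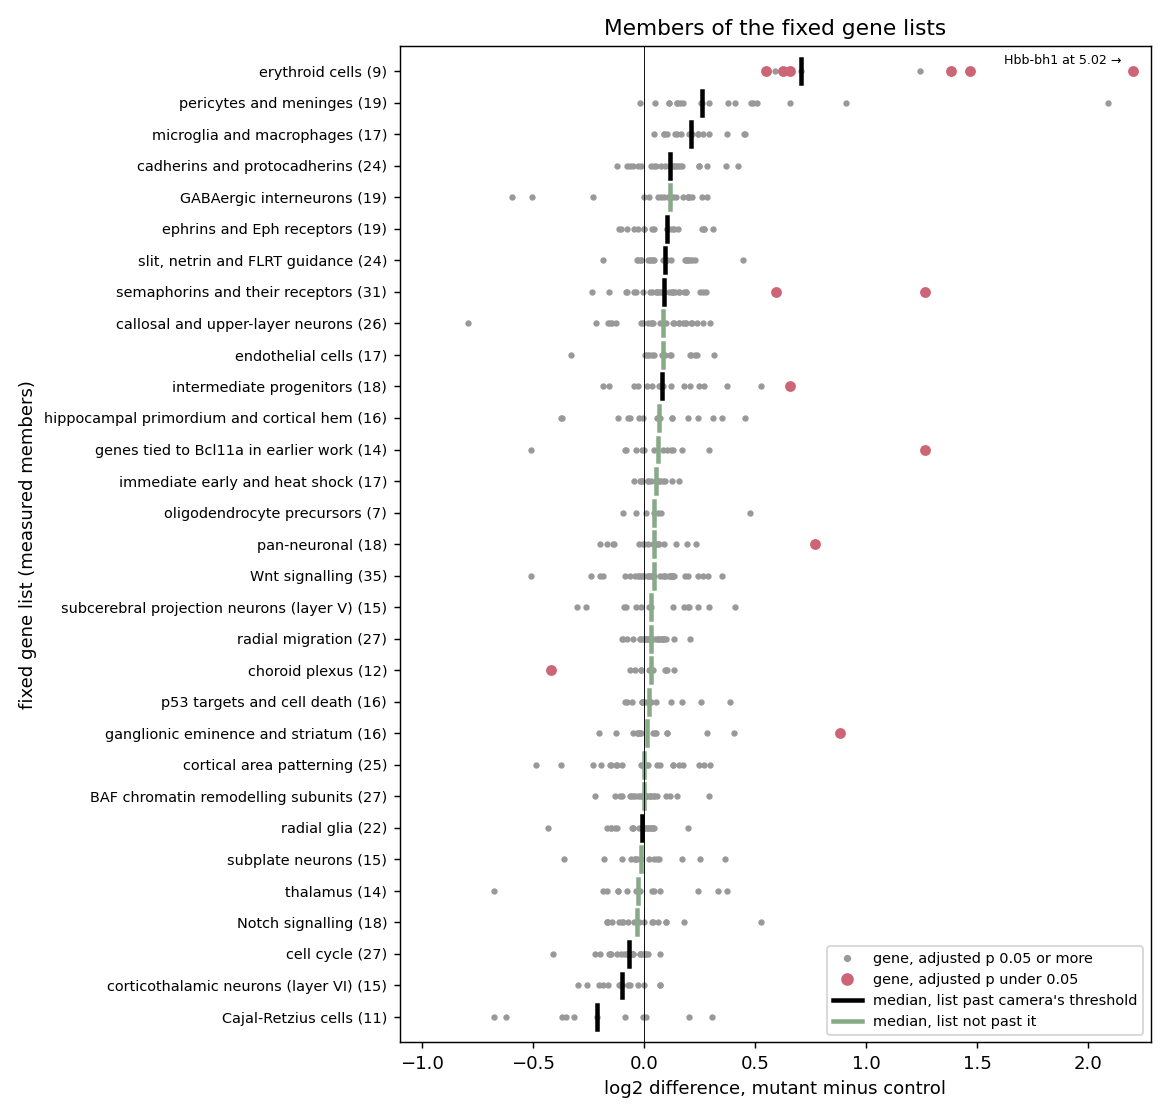
Each line is 1 of the 31 fixed gene lists, each point a measured member and the x axis its log2 difference of mutant minus control. Large red points are genes with an adjusted p under 0.05, and the bar is the list median, black where camera called the list. The erythroid list stands apart with a median of 0.71, and Hbb-bh1 at 5.02 is drawn at the edge of the axis.

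By camera 12 of the 31 lists passed, 8 higher and 4 lower, and 11 of them lost the call with an estimated correlation. For the slit, netrin and FLRT list and the corticothalamic list that correlation was 0.0057 and 0.0097, below the preset 0.01. The loss of these calls is thus not due to a higher correlation between genes. Splits of the arrays that mixed the genotypes gave 3 to 8 lists by camera with the preset correlation, although part of the genotype difference remains in such splits. Of the 19 lists that did not pass with the real groups, 4 held a gene that passed. Syt4, a synaptotagmin gene, rose by 0.77 among pan-neuronal genes (list adjusted p = 0.554). Ebf1, a transcription factor gene of the ganglionic eminence and striatum list, rose by 0.88 (list 0.850) and is also among the 200 genes nearest to Bcl11a. Car12 belonged to the choroid plexus list (0.572), and Sema3c to the genes tied to Bcl11a in earlier work (0.160). The Bcl11a list holds Sema3c because of this study and is not independent evidence either. Adjusted over the list alone it held 2 higher genes, Sema3c and Bcl11b, and the 3 lists before it held 1 each, the gene named. Without control replicate 2 the Syt4 call was lost (adjusted p = 0.0578), and Ebf1 passed only without control replicate 3 (up to 0.0952 in the other fits).

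Of 57 calls, 17 passed in each of the 6 fits that left out 1 array, 10 in none, and all 57 kept their sign. The count was 20 without control replicate 2 or mutant replicate 2, 25 without mutant replicate 1, 33 without mutant replicate 3, and 24 with the embryos' sex as a covariate. Of the 27 named genes that passed, 11 did not pass with that covariate (adjusted p = 0.0606 to 0.180), which were Tfap2d, Egln3, Gipr, Myc, Car12, Shc3, Nrp2, Neurod4, Ebf1, Rhag and Epb42. Their log2 differences moved by at most 0.022.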

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

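Leaving out the erythroid list, alone or with mutant replicate 1, was chosen after the data were seen. Bcl11a and Sema3c passed in all 18 other settings, with log2 differences of -0.88 to -0.80 (highest adjusted p 0.0251) and 1.16 to 1.34 (0.0215). No named gene or list past the threshold changed its direction of test, and 339 results of named genes kept their call while 91 lost it. The number of genes was 20 to 50 when 1 array was left out, with fewer arrays in the fit. It was 61 with quantile normalization and 64 with median centring, which left the median of all genes at 0.02 and 0.03. It was 217 with array weights, 24 with sex as a covariate, 13 with all probe sets counted singly, 107 at an adjusted p under 0.1 and 136 at an unadjusted p under 0.001. It was 49 without the erythroid list and 20 without that list and mutant replicate 1. With the replicate number as a block (replicate block) it was 34, of which 29 were among the 57, and 9 of the 27 named calls did not pass. Same-numbered arrays deviated from their group means with correlations of 0.03, -0.14 and 0.08, and 1 of the 3 numbers had its own number as best partner, which gives no sign that the numbers pair the samples. Of the lists, 1 passed with an estimated correlation and 3 with fry, and 9 to 14 under the other settings. The directions that turned were all of lists that did not pass, and the cause was not tested. The values given are list medians, and in 4 lists the sign of the median, the mean or camera's direction differed: BAF subunits, subplate, cortical hem and choroid plexus. Over the fits without 1 array, medians ranged from -0.081 to 0.0079 for Notch signalling, 0.012 to 0.058 for pan-neuronal genes, -0.0084 to 0.042 for subplate, 0.032 to 0.17 for GABAergic interneurons, -0.027 to 0.058 for ganglionic eminence, 0.0099 to 0.13 for cortical hem, -0.043 to 0.069 for choroid plexus, -0.0084 to 0.17 for endothelial cells and -0.0069 to 0.075 for oligodendrocyte precursors. The cortical hem list turned at 0.061 with quantile normalization, 0.066 with an intensity trend, 0.086 with sex and 0.066 with fry. The subplate list turned at 0.016 with the lower filter on dim genes, 0.044 among genes at or above the median level and -0.012 with fry. Layer V turned at 0.0083 and thalamus at 0.16 among genes at or above the median level, where fewer genes were tested. Layer V turned at 0.015 and oligodendrocyte precursors at -0.00057 with array weights. Endothelial cells turned at -0.0084 without mutant replicate 1, whether or not the erythroid list was also left out. With fry, area patterning turned at -0.0012 and BAF subunits at -0.0020. For dim genes the signal over background limits what can be seen, and Rhag, at 4.74 in controls, lies close to the lowest values of the arrays.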

Other observations

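The tests of blood of unchanged make-up, of cross-hybridization, of Hba-x as a linked gene, of tissue carried by mutant replicate 1 and of a lost repressor were chosen after the results were seen. The setting without the erythroid list and mutant replicate 1 was also added after the data were seen, although its test was written before its result, and the other tests were written before theirs.

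Signalling and patterning lists held genes that passed only adjusted over the list alone, and no list in this paragraph passed by camera. Among 25 area patterning genes (camera adjusted p = 0.338), Lmo4, Cdh8 and Efna5 were higher, at 0.30, 0.25 and 0.27, and Dmrt3 and Etv5 were lower, at -0.38 and -0.48. Dmrt3, a gene of the medial cortex, was also the 1 lower gene of 16 for hippocampal primordium and cortical hem (0.926). Wnt7b at 0.29 and Dkk3 at 0.26 were higher among 35 Wnt genes (0.395), and Dll3 at 0.53 among 18 Notch genes (0.213). Of 14 thalamus genes (0.293), Slc17a6 at 0.37 and Lhx9 at 0.33 were higher and Calb2 at -0.68 was lower. Tmem163 at 0.37 was higher among 15 subplate genes (0.873). No gene passed, adjusted over the list alone, among 19 genes of GABAergic interneurons (0.173), where Npy was at -0.60 and Ackr3 at 0.26. The same held for 27 radial migration genes (0.561), 16 p53 targets and cell death genes (0.554), 17 immediate early and heat shock genes (0.359), 27 BAF subunits (0.365) and 7 genes of oligodendrocyte precursors (0.717).

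Some genes outside the naming rule also passed and are given here after their values were seen. Rit2, a neuronal small GTPase, rose by 0.87, Lratd1 by 0.81, Fam160a1 by 0.76 and Dlk1, a Notch ligand relative, by 0.61, each in all 6 fits that left out 1 array. The predicted gene Gm32061 rose by 1.77. It passed in 2 of those 6 fits.

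Red cell genes were higher in the mutant arrays. More blood of unchanged make-up in the mutant tissue is argued against, since the log2 difference of Hbb-bh1 exceeded the median of those of Alas2, Hba-x and Hbb-y by 4.31 ± 0.35 (SE), and cross-hybridization of Hbb-y is too, since the highest control ratio to the level it needs was 0.0189. The 6 erythroid genes that rose are not as a set linked to Bcl11a, since only 1 of them, Hba-x, lay among the 200 genes around it. A linked variant that acts on genes elsewhere was not tested. For Hba-x itself linkage cannot be told apart from an effect of the mutation. Of the 200 neighbours, 1%, Hba-x and Ebf1, passed against 0.274% elsewhere (one-sided Fisher's exact p = 0.109). Whether more blood raised the non-globin genes also stays open. Adult globin probe sets, shared by several genes and at 12.6 to 12.9, differed by 0.16 ± 0.11 (SD over 4 probe sets, not over embryos). The alpha globin probe sets differed by 0.26 and 0.25 and the beta globin ones by 0.08 and 0.05, and none passed. Their mutant means lay 0.90 to 1.03 below the highest array value, further than the distance set beforehand as too near it. Release of embryonic globins in erythroid cells without Bcl11a, a known globin repressor, stays open too. Hbb-bh1, Hbb-y and Hba-x exceeded these adult probe sets by 2.17 on average. Hbb-bh1 carries this excess at 4.85, against 1.22 for Hba-x and 0.43 for Hbb-y. The excess may be overstated if a rise of the adult probe sets was compressed, although they lay outside the limit set beforehand. The sources used here do not say that blood cells carried the deletion.

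Genes of pericytes and meninges were high in mutant replicate 1, where Dcn read 10.49 and Igf2 10.63. The list median was 0.071 without this array and 0.263 with it, so most of its size rests on this array. A smaller rise with genotype stays open, although the test set beforehand counted a median below 0.5 of the full value against it, since the list still passed camera without the array (adjusted p = 0.0114; with all arrays, adjusted p = 0.512 with an estimated correlation) and Dcn, at 8.32 and 7.27, was above every control in the other two mutants. Meningeal or vascular tissue in this sample was not tested independently: that 84.2% of the 19 genes, none of them held by another list, were highest in this array restates the pattern.

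More genes were higher than lower among the calls. Without the erythroid genes and mutant replicate 1, 80% of the 20 calls were higher, a share that the test set beforehand counted against them as the whole cause. This share of so few calls was not tested against the 60.3% of positive differences among all genes, so no conclusion is drawn. The scaling of the arrays stays open: 86.9% were higher under quantile normalization and 90.6% under median centring, but on values that RMA had already scaled these moved the median of all genes only from 0.0187 to 0.0196 and 0.0269, too little for a test. The loss of a repressor was not tested either, since the excess of 86.0% over the 60.3% of positive differences among all genes (two-sided exact binomial p = 3.40e-05) restates the pattern, and the share was 72.3% without control replicate 1.

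There are 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. The real split gave 57 genes and 12 lists, and 1 split, the real one, gave as many of either. The highest of the others gave 4 genes, in the split that follows sex, and 8 lists. Each split that mixed the genotypes called at least 3 lists. These splits are unbalanced for genotype, so part of the genotype difference remains in them. They therefore do not show how many lists camera would call without a genotype difference.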
